A study of Mus musculus with 6 samples.

How the data were processed

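Total RNA of cultured mouse sarcoma cells was sequenced in 6 libraries, 3 labelled as wild-type control and 3 as Setd1a knockout. Per the labels' protocols, RNA was extracted with a column kit and libraries were built by BGI's standard procedure. The authors deposited a single table of raw counts, whole numbers of reads per Ensembl gene for 55471 genes in 6 columns, with no normalization. Per the submitters' processing notes, STAR, featureCounts and DESeq were used with the mm10 build; versions, the annotation release, the strand setting, the rule for reads that match several genes or places, and the role of each tool are not given in the sources used here. Without the strand setting, reads of overlapping or antisense genes cannot be told apart, and reads shared by paralogs may be split or left out. The sample titles also carry a tag for each group, whose meaning the labels do not give. The tag divides the libraries as the knockout label does, so whatever it marks cannot be told apart from the knockout. Groups and replicate numbers were taken from the sample titles, and columns were matched to samples by name.

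Gene symbols and coordinates were taken from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names. Of the 55471 identifiers, 55144 matched and 327 did not; the unmatched held at most 0.0204% of the counts of any library. Of the 13044 genes tested, 13039 had a position. Library totals lay between 17749533 and 18272622 counts. At that depth a gene at 1 CPM has about 18 reads per library, so genes near that level have wide counting error. No pair of libraries within a group agreed within sampling noise: the chi-square statistic per degree of freedom over genes with at least 60 counts lay between 19.2 and 35.5.

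Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, edgeR's filter on low counts by group, which removed at most 0.127% of the counts of any library, and the two-sided quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM are counts scaled to the TMM-adjusted library size, and logged CPM used a prior count of 2. The comparison of the 3 knockout and 3 control libraries without pairing was fixed before the data were examined, with the replicate number as a block (the paired test) as its alternative. Whether the numbers pair the libraries was checked from the correlation of deviations from the group means: it was 0.15, 0.46 and 0.38 for libraries of the same number, and between -0.45 and 0.05 for libraries of different numbers. All 3 same-number values lay above 0.1, the limit set for treating the numbers as pairs. The labels do not say what a number stands for, so the pairing comes from the data alone. Deviations within a group sum to 0, so the different-number values follow in part from the same-number ones and are not separate evidence. With 3 libraries per group few other pairings exist, so the check is weak. The fits with and without the block had been computed together before that limit was applied. The biological coefficient of variation was 0.143 without the block and 0.0960 with it.

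Gene lists were written before the data were examined: 36 lists of pathways, complexes and markers of other cell types, of which 34 had at least 5 tested members. Of the symbols written, 9 did not match the annotation. Lists and chromosomes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, beside an estimated correlation. The estimated version takes its degrees of freedom from the libraries and not from the number of genes, so with so few libraries it has little power. Lists were also tested with the directional fry test. Members passing the test were counted over all genes tested and adjusted over the list alone. The genes to be named were Setd1a, up to 12 genes with the largest increases and 12 with the largest decreases among called genes with at least 5 CPM in the higher group and no overlap between groups, leaving out predicted genes and clones, and up to 4 members of each list with the smallest raw p in the test without pairing. Since that test called no gene, the same rule was applied to the paired test after the data were examined. Some genes selected by the rule are not reported here. The mitochondrial gene mt-Cytb was also chosen after its values were seen. Levels of single values per library were compared by exact two-sided permutation tests, for which the smallest possible p is 0.1.

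The steps were tested on simulated counts for 12771 tested genes, with 200 genes changed by known amounts. Means were those fitted to the real libraries in the paired test, so differences between pairs were built into the counts. Dispersions followed the trend of that fit over expression level and not single genes. For the comparison of knockout and control, the test without pairing recovered 11.9% of genes changed by a log2 amount of 0.6, 67.2% of those changed by 1 and 92.4% of those changed by 2. The paired test recovered 52.2%, 86.6% and 97.0%, with 8 false calls. With no changed genes, both called 0 genes and 0 lists. The higher recovery of the paired test follows from the pair differences built into the counts. It does not show whether pairing suits the real libraries. The simulated genes were independent of each other, unlike real genes.

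Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no low-count filter, a minimum mean of 5 CPM, each library left out in turn, and the replicate block. Added after the data were examined were variants of the paired test with the same tools and filters, with each pair left out, and with an offset for GC content and exonic length fitted by loess in each library. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.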

Results

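RNA sequencing counted transcripts in cultured mouse undifferentiated pleomorphic sarcoma (UPS) cells. The cells were a line derived from a soft-tissue tumour and labelled as metastatic, with libraries labelled as control or as Setd1a knockout. Setd1a encodes a histone methyltransferase, the catalytic subunit of one of the COMPASS complexes that methylate histone H3 at active promoters. There were 3 control libraries and 3 knockout libraries, numbered 1 to 3 in each group. The comparison asked how gene expression differed between the libraries labelled as knockout and the controls. Total counts per library lay between 17749533 and 18272622, and 13044 of the 55471 genes in the table had enough counts to be tested. At least 1 count was found for 19114 ± 189 genes in the controls and 19849 ± 295 in the knockouts (SD, n = 3; exact two-sided permutation p = 0.1). No label says whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

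The Setd1a transcript (ENSMUSG00000042308, chromosome 7, positions 127776670 to 127800122 of GRCm38, plus strand) was present in every library. It averaged 73.3 ± 2.17 CPM (counts scaled to library size; SD, n = 3) in the controls and 59.4 ± 8.17 CPM (SD, n = 3) in the knockouts. The control libraries held 71.0, 75.3 and 73.5 CPM and the knockout libraries 53.2, 68.7 and 56.3 CPM, so every knockout library lay below every control library. The exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 can give. The log2 change was -0.30 ± 0.12 (SE), with an adjusted p of 0.426 in edgeR's quasi-likelihood test. Of the exonic bases of Setd1a, 51.8% are shared with the overlapping gene Gm49388, which held 1 count in all libraries together. Reads of the shared bases may have been left out of the counts, so the level and change of Setd1a are uncertain. The counts do not resolve exons, so they do not show whether the transcript carried a disrupted coding sequence.

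**Figure D1:**
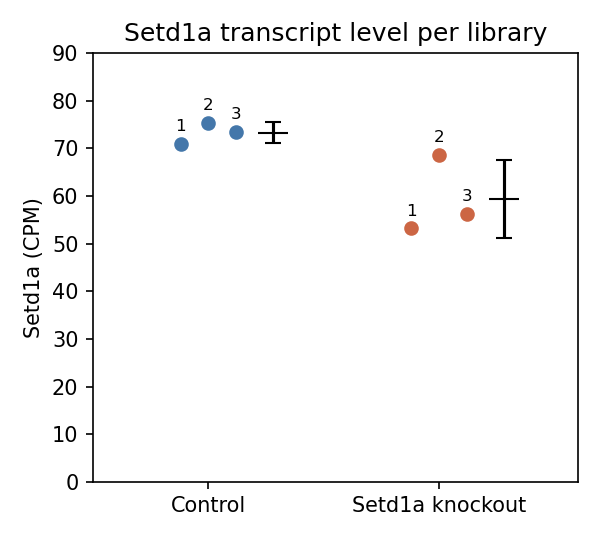
Setd1a transcript level (vertical axis, CPM from 0) in the 3 control and 3 knockout libraries, each point a library marked with its replicate number, with the mean and SD of each group beside the points. The controls sit between 71.0 and 75.3 CPM and the knockouts between 53.2 and 68.7 CPM.

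The genes that rose in the knockout libraries included interferon-inducible genes, neuronal genes and a cornified envelope gene, and those that fell included a kinase, an adenylyl cyclase and an elastic-fibre protein. In the paired edgeR test, which compared libraries of the same replicate number, 187 genes were higher and 111 were lower in the knockout at an adjusted p under 0.05. Of these, 48 were at least 2-fold higher and 6 at least 2-fold lower. The median change was 1.72-fold among the higher genes and 0.679-fold among the lower ones. The edgeR test without pairing called 0 genes higher and 0 lower, 0 of them at least 2-fold, with a smallest adjusted p of 0.124. At an unadjusted p under 0.05 that test had 718 genes higher and 588 lower. Without pairing, DESeq2 called 93 genes higher and 40 lower and limma-voom called 0 and 0 (676 higher and 597 lower at an unadjusted p under 0.05); 130 of the 133 DESeq2 calls were also called, in the same direction, by the paired edgeR test. The calls varied with the pairs used: without pair 3 the paired test called 0 genes in either direction. All 298 genes kept their direction, but they had been chosen with pairs 1 and 2 included, which largely fixed that outcome. Without pair 1 the paired test called 507 higher and 207 lower, with 279 of the 298 among them. Without pair 2 it called 140 higher and 54 lower, with 143 of the 298 among them. All changes named from here on are those of the paired edgeR test, with Benjamini-Hochberg adjusted p-values, and no gene passed the adjusted threshold in the edgeR test without pairing.

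Among called genes with at least 5 CPM in the higher group and no overlap between the groups, Ifi207 had the largest increase (chromosome 1, 173723427 to 173741747). This member of the interferon-inducible PYHIN family went from 1.61 ± 0.83 CPM in the controls to 8.42 ± 4.62 CPM in the knockouts (SD, n = 3), a log2 change of 2.27 ± 0.44 (SE, adjusted p = 0.0363). Its reads may be shared with the near-identical members of its family, so its level is uncertain. L1cam (chromosome X, 73853778 to 73896105), a neural cell adhesion molecule, rose 3.72-fold, from 2.13 ± 0.95 to 7.90 ± 2.08 CPM (SD, n = 3; adjusted p = 0.0184). Sprr1a, a cornified envelope protein, rose 3.28-fold, and Syn1, which encodes the synaptic vesicle protein synapsin I, rose 2.32-fold. Hspb1 (chromosome 5, 135887919 to 135889563), a small heat shock protein, had the smallest adjusted p of the higher genes named here, 0.0155, shared with Sprr1a and Ccl2, and went from 6.91 ± 0.46 to 15.9 ± 1.46 CPM (SD, n = 3). Qpct, which encodes glutaminyl cyclase, rose 2.36-fold, the zinc finger gene Zfp37 2.23-fold, Esp15 2.26-fold and Fam167a 2.16-fold.

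Under the same limits, Hunk (chromosome 16, 90386013 to 90499553), a serine/threonine kinase, had the largest decrease, from 15.4 ± 2.35 CPM in the controls to 7.67 ± 0.998 CPM in the knockouts (SD, n = 3), a log2 change of -1.0 ± 0.12 (SE, adjusted p = 0.0162). The adenylyl cyclase gene Adcy8 fell to 0.555 of its control level and Cntln, which encodes the centriolar protein centlein, to 0.559. Fbn2 (chromosome 18, 58008623 to 58210487), which encodes the microfibril protein fibrillin-2, went from 135 ± 27.7 to 77.1 ± 18.3 CPM (SD, n = 3), a log2 change of -0.82 ± 0.10 (SE, adjusted p = 0.0155). Gatb, a subunit of the mitochondrial glutamyl-tRNA amidotransferase, fell to 0.579 of the control level, Cep131, a centriolar satellite protein, to 0.589, Kctd15 to 0.596, Tmem143 to 0.611, the pseudokinase gene Trib2 to 0.612 and Bola1, a mitochondrial protein of iron-sulfur cluster assembly, to 0.614. Zfp213 fell to 0.564, but 46.5% of its exonic bases are shared with Gm26695, so its counts are uncertain.

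**Figure D2:**
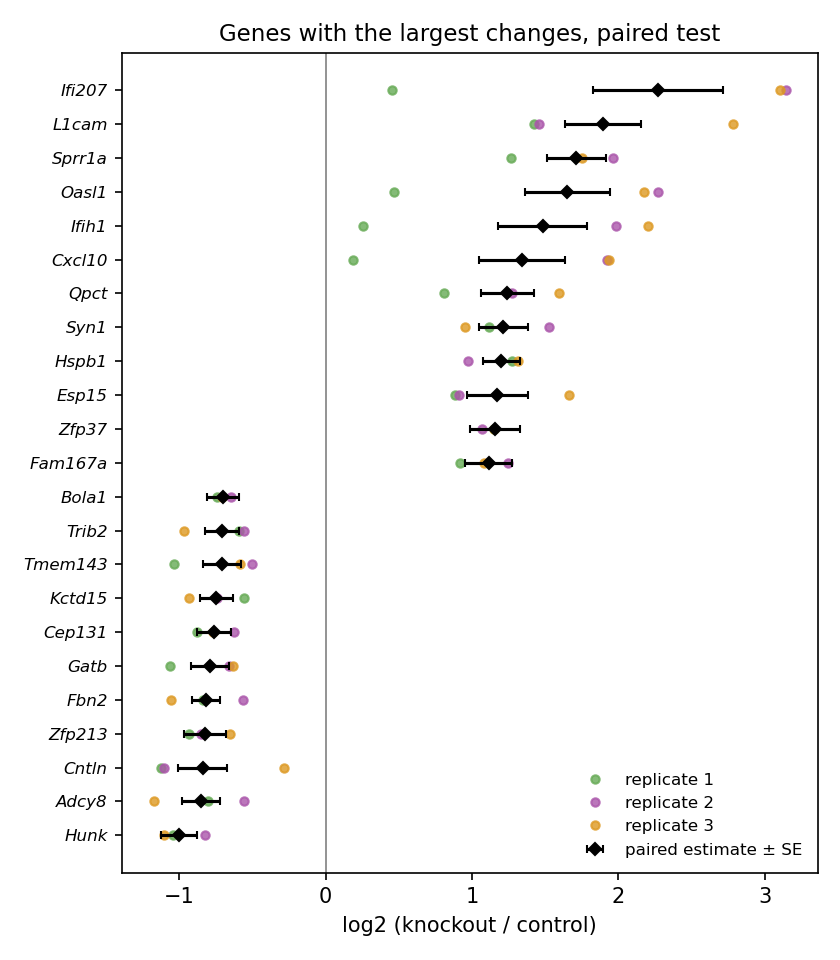
Log2 ratio of knockout to control (horizontal axis) for 12 genes with the largest increases and 11 of those with the largest decreases in the paired test, among genes with at least 5 CPM in the higher group and no overlap between the groups, leaving out predicted genes and clones. Diamonds with bars are the paired estimates with SE and coloured circles are the ratios within replicates 1, 2 and 3. Every gene lies on one side of 0 in all 3 pairs, which the rule of no overlap between the groups fixes. Ifi207, Oasl1, Ifih1 and Cxcl10 have a smaller ratio in replicate 1 than in the others. So do L1cam, Sprr1a, Qpct, Esp15 and Fam167a, while the higher genes Syn1, Hspb1 and Zfp37 do not.

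As a list, genes induced by interferon were higher in knockout replicates 2 and 3 and not in replicate 1. The mean level of the 46 measured genes of the interferon response list was 3.88, 3.33 and 2.69 log2 CPM in control replicates 1, 2 and 3, and 3.10, 4.97 and 4.97 log2 CPM in the knockout replicates (exact two-sided permutation p = 0.3). The median log2 ratio of knockout to control over the list was -0.83 in pair 1, 1.69 in pair 2 and 2.44 in pair 3. Single members differed in pair 1, with log2 ratios of 0.47 for Oasl1, 0.25 for Ifih1 and -0.14 for Ifit1. Of the 46 genes, 3 passed the paired test over all genes tested, all higher, and 4 did so when adjusted over the list alone. They included Oasl1, an oligoadenylate synthetase-like protein that restrains interferon production, which rose 3.14-fold from 22.1 ± 5.35 to 72.7 ± 29.1 CPM (SD, n = 3; adjusted p = 0.0291), and Ifih1, which encodes the RNA sensor MDA5 and rose 2.80-fold (adjusted p = 0.0419). Ifit1 averaged 21.1 ± 10.96 CPM in the controls and 57.0 ± 23.1 CPM in the knockouts (SD, n = 3), with an adjusted p of 0.0838, and its reads may be shared with other Ifit genes. The list was called higher by camera with its preset correlation of 0.01 (adjusted p = 6.92e-26) and not with an estimated correlation (adjusted p = 0.531 without pairing and 0.667 with it). Adjusted p-values of lists are those of the test without pairing unless stated.

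**Figure D3:**
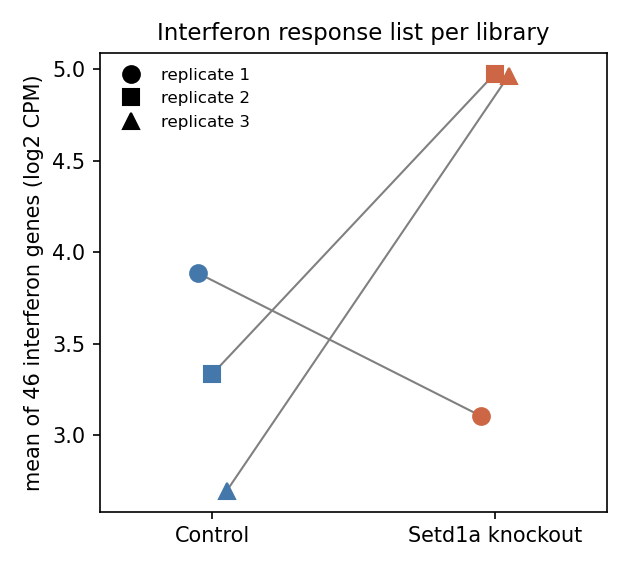
Mean level of the 46 measured interferon response genes (vertical axis, log2 CPM) in each library, with control and knockout libraries of the same replicate number joined by a line. The line falls from 3.88 to 3.10 for replicate 1 and rises for replicates 2 and 3, to 4.97 in both.

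Antigen presentation genes and chemokines were also among the genes that rose. Of 22 antigen presentation genes, 7 rose and 0 fell in the paired test, and 12 rose when adjusted over the list alone; their median log2 ratio was 0.05 in pair 1, 0.91 in pair 2 and 0.89 in pair 3. Psmb8, an immunoproteasome subunit, rose 4.57-fold from 0.97 ± 0.34 to 4.71 ± 2.71 CPM, Cd274, which encodes PD-L1, rose 2.71-fold, and Nlrc5, the transactivator of MHC class I genes, rose 1.64-fold from 19.8 ± 1.23 to 33.4 ± 9.66 CPM (SD, n = 3). The list's adjusted p was 5.80e-10 with the preset correlation and 0.531 with an estimated correlation. Of 25 inflammatory cytokines and NF-kB targets, 4 rose and 0 fell, and 8 rose and 1 fell when adjusted over the list alone. The monocyte chemokine gene Ccl2 (chromosome 11, 82035571 to 82037453) went from 28.9 ± 3.27 to 53.02 ± 1.995 CPM (SD, n = 3), a log2 change of 0.88 ± 0.10 (SE, adjusted p = 0.0155), and its neighbour Ccl7 rose 1.98-fold. Cxcl10, an interferon-inducible chemokine, rose 2.54-fold, while Ccl5 had an adjusted p of 0.0525 at 2.38-fold. This list's adjusted p was 3.50e-08 with the preset correlation and 0.245 with an estimated correlation.

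Of 10 measured epithelial markers, 3 rose and 0 fell, and 5 rose when adjusted over the list alone. Among them, the desmosomal gene Dsp went from 12.2 ± 2.23 to 21.3 ± 2.62 CPM (SD, n = 3; adjusted p = 0.0203) and the serine protease inhibitor gene Spint2 from 1.10 ± 0.12 to 2.61 ± 0.50 CPM (SD, n = 3; adjusted p = 0.0363). Of 31 matrix proteases and inhibitors, 4 rose and 0 fell, and 5 rose and 1 fell when adjusted over the list alone. The gelatinase gene Mmp2 rose 1.45-fold from 61.5 ± 5.598 to 90.2 ± 21.2 CPM (SD, n = 3) and the tissue plasminogen activator gene Plat 1.37-fold. Camera called both lists higher with the preset correlation (adjusted p = 0.000145 and 0.0299) and neither with an estimated correlation (adjusted p = 0.531 for each); without knockout replicate 1 the protease list was no longer called (adjusted p = 0.211), nor was it with a minimum mean of 5 CPM (adjusted p = 0.131). Collagens and matrix assembly genes went both ways and were not called as a list (adjusted p = 0.172), but were called higher with a minimum mean of 5 CPM, without control replicate 2 and without knockout replicate 3. Of the 48 measured, 5 rose and 3 fell in the paired test, and 14 rose and 6 fell when adjusted over the list alone. Nid1, a basement membrane protein, rose 1.44-fold from 189.9 ± 25.4 to 273.8 ± 32.4 CPM (SD, n = 3), Col7a1 rose 1.73-fold and Col5a3 1.65-fold, while Fbn2 fell.

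Transcripts encoded in the mitochondrial genome took a larger share of the counts in the knockout libraries, 3.71% ± 0.22 against 2.80% ± 0.28 in the controls (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible). Of 13 measured members of that list, 3 rose and 0 fell in the paired test, and 5 rose when adjusted over the list alone. The respiratory complex I gene mt-Nd1 rose 1.52-fold from 6022 ± 919 to 9132 ± 1436 CPM (SD, n = 3), mt-Nd2 rose 1.53-fold and the small ribosomal RNA gene mt-Rnr1 1.46-fold. The mitochondrial chromosome was the 1 chromosome of 22 whose genes shifted together by camera (adjusted p = 7.79e-05 with the preset correlation and 0.582 with an estimated correlation; 0 chromosomes without control replicate 3). Of the 11 mitochondrial mRNAs measured, 5 held under 10 CPM in both groups; reads that also match nuclear copies of these genes may not have been counted.

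Most measured nuclear genes for ribosomal proteins, respiratory subunits and cholesterol synthesis had log2 changes below 0, and few passed the test singly. Of 79 cytosolic ribosomal protein genes, 76 had a log2 change below 0, the median change was -0.11, and 0 passed the test singly, also when adjusted over the list alone. Rpl28 averaged 801.6 ± 65.5 CPM in the controls and 666.8 ± 31.9 CPM in the knockouts (SD, n = 3; adjusted p = 0.0983). Of 25 cholesterol synthesis genes, 22 lay below 0 and 1 fell, Pmvk, which encodes phosphomevalonate kinase, to 0.695 of the control level; 7 fell when adjusted over the list alone. The lanosterol synthase gene Lss was at 0.827 of the control level (adjusted p = 0.0831). Of 59 nuclear oxidative phosphorylation genes, 43 lay below 0 and 0 passed the test singly; Uqcrq averaged 92.3 ± 12.2 CPM in the controls and 72.9 ± 10.97 CPM in the knockouts (SD, n = 3; adjusted p = 0.0769). Of 30 homologous recombination and Fanconi anaemia repair genes, 20 lay below 0 and 0 passed the test singly, with 3 lower when adjusted over the list alone; the adjusted p was 0.0589 for Fancd2 and 0.0728 for Brca2. Camera called these 4 lists lower with the preset correlation, at adjusted p-values of 0.000145 for ribosomal proteins, 0.00159 for cholesterol synthesis, 0.0365 for oxidative phosphorylation and 0.0263 for repair, and none of them with an estimated correlation (adjusted p = 0.931, 0.879, 0.931 and 0.531). The ribosomal protein call was lost without control replicate 3 (adjusted p = 0.413) or knockout replicate 2 (0.297), and the cholesterol call without control replicate 3 (0.106) or knockout replicate 1 (0.290). The oxidative phosphorylation call was lost without control replicate 3 (0.934) or knockout replicates 1 (0.211) or 2 (0.655), and the repair call without control replicates 1 (0.139) or 2 (0.0562) or knockout replicate 3 (0.0583). These losses came from tests without pairing. Within pairs, the median log2 ratio of each of the 4 lists lay below 0 in all 3 pairs, at -0.07, -0.11 and -0.16 for ribosomal proteins. With a minimum mean of 5 CPM, the oxidative phosphorylation and repair lists were not called (adjusted p = 0.131 for each).

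**Figure D4:**
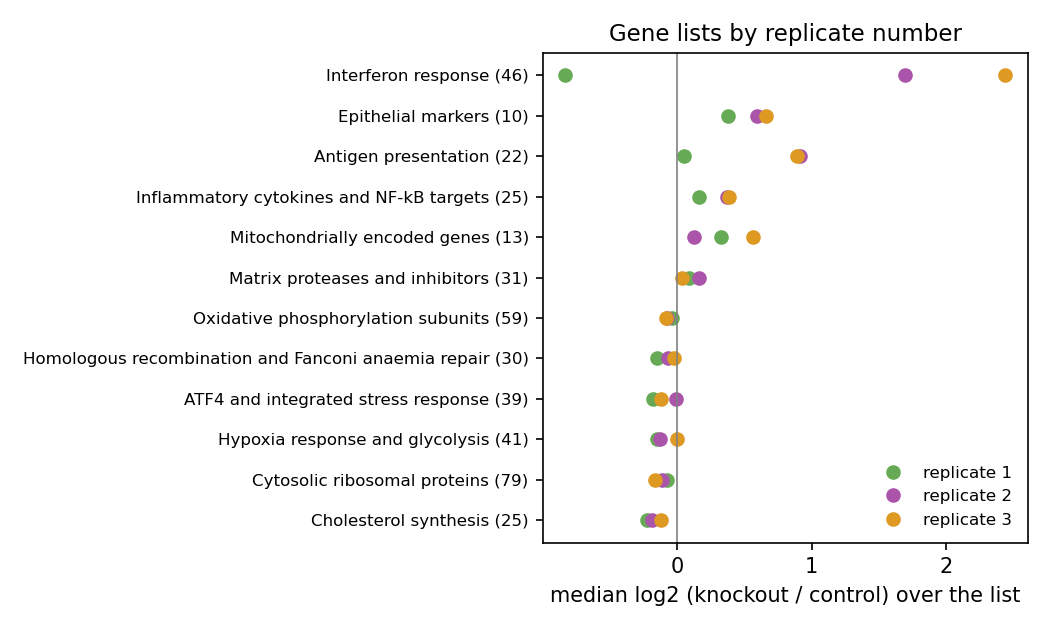
Median log2 ratio of knockout to control (horizontal axis) over each of the 12 gene lists called by camera with the preset correlation in the paired test, with the number of measured genes in brackets. Each circle is a replicate number. The interferon list is at -0.83 in replicate 1 and at 1.69 and 2.44 in replicates 2 and 3, and the lower lists lie close to 0.

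In all, 6 lists of the 34 tested were called higher and 4 lower without pairing; with pairing, the same 6 were higher and 6 were lower, the added ones being the integrated stress response list (adjusted p = 0.0179) and the hypoxia and glycolysis list (adjusted p = 0.0279). With an estimated correlation 0 lists were called in either test, the smallest adjusted p being 0.245 without pairing and 0.523 with it. That version of camera also has few degrees of freedom with 6 libraries, so a missed call need not come from correlation between genes. For oxidative phosphorylation with pairing, the estimated correlation was -0.017, yet camera's unadjusted p went from 0.00525 to 0.0726. The directional fry test called no list either, with a smallest adjusted p of 0.0932 without pairing and 0.0722 with it. Fry's mixed version, for changes in either direction within a list, was not adjusted over the lists. Its smallest unadjusted p was 3.24e-06 without pairing, for heat shock chaperones, and 0.00119 with it, for Hox genes. Among the 24 genes of the COMPASS complexes and the opposing demethylases, 0 passed the test singly and the list was not called (adjusted p = 0.5996). The demethylase gene Kdm5a had a log2 change of 0.19 ± 0.08, Kdm1a -0.17 ± 0.08 and Men1, a COMPASS-associated tumour suppressor, -0.19 ± 0.08 (SE, adjusted p = 0.258, 0.287 and 0.213). Most markers of macrophages and of endothelium were near the floor, with a median marker at 0.0458 and 0.239 CPM in the knockout libraries, while 3 of 18 and 4 of 17 passed the low-count filter. The endothelial markers summed to 40.3 ± 3.45 CPM in the controls and 50.3 ± 7.02 CPM in the knockouts (SD, n = 3; exact two-sided permutation p = 0.2).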

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

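The variants of the paired test were chosen after seeing the data. Without pairing, RLE or upper-quartile factors, limma-voom and a minimum mean of 5 CPM left the counts of called genes at 0. DESeq2 called 93 genes higher and 40 lower (34 and 2 at least 2-fold), and no low-count filter gave 62 and 12 (45 and 2 at least 2-fold). Leaving out single libraries gave 0 to 30 higher and 0 to 1 lower genes (0 to 27 and 0 to 1 at least 2-fold). The calls came without knockout replicate 1, and 19 of those 31 genes belonged to the interferon or antigen presentation lists. The others included the interferon-inducible gene Ifi207, which was not on those lists. The replicate block gave 187 and 111 (48 and 6 at least 2-fold). It changed no other call than those of single genes and the 2 lists added above. Within the paired test, no low-count filter gave 411 higher and 356 lower (124 at least 2-fold higher) and the GC and length offset 468 and 437 (93 at least 2-fold higher); both kept all 298 genes of the paired test. DESeq2 with the replicate block gave 26 genes at least 2-fold higher, and shared 224 of the 298. A minimum mean of 5 CPM gave 8 at least 2-fold higher and 1 lower, with fewer genes tested. Leaving out a pair gave 0 to 507 higher and 0 to 207 lower genes (0 to 197 and 0 to 7 at least 2-fold). Without pair 2 there were 54 lower genes, and without pair 3 there were 0 called genes. All 298 genes kept their direction without pair 3, which their selection with the other pairs included had largely fixed. Setd1a kept its direction and missed the threshold in every alternative of the test without pairing, with log2 changes from -0.41 to -0.22 and adjusted p from 0.0913, with the replicate block, to 0.743. Within the paired test it passed with the GC and length offset (log2 change -0.31, adjusted p = 0.0365). An estimated correlation left 0 lists higher and 0 lower and 0 chromosomes, also with the replicate block. Lists called higher numbered 6 to 8 with a library left out, with collagens and matrix assembly, YAP and TAZ targets, immediate early genes or NRF2 targets added in some. Lists called lower numbered 9 with no low-count filter and 2 with a minimum mean of 5 CPM (10 and 3 in the paired test), and 3 to 7 with a pair left out. Chromosomes called numbered 3 with a minimum mean of 5 CPM and 0 to 1 with a library left out. Of the genes named, mt-Cytb changed sign, to -0.013, in the paired test without pair 3. The other gene values kept their sign, 440 of them also their side of the threshold in the paired test, while 72 lost a call and 19 gained one; without pairing, 641 stayed on their side and 118 gained a call. For the values that moved, the cause was not tested unless fewer genes or samples account for it. Genes near 1 CPM rest on about 18 reads per library.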

Other observations

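The tests of macrophages, of variation between libraries and of even mitochondrial increases were chosen only after the values were seen, as were the lists of mitochondrial translation factors and of neuronal genes, which left out the members already seen. Beyond the genes described above, the paired test called single genes of further lists. Of these lists only that of the integrated stress response was called in the main settings, lower and with pairing. The smallest adjusted p of the others in either test was 0.132, for p53 targets. Among alternatives without pairing, the integrated stress response list was called lower with no low-count filter, without control replicate 2 and without knockout replicate 3. Immediate early genes were called higher without knockout replicate 1 and NRF2 targets without knockout replicate 2. Of 21 heat shock chaperones, 3 rose, all small heat shock proteins: Hspb1, Cryab (1.27-fold, from 156.7 ± 14.3 to 199.0 ± 17.4 CPM) and Hspb8 (1.30-fold; SD, n = 3), while 12 of the 21 lay below 0 and 1 fell when adjusted over the list alone. The p53 targets Phlda3 and Pmaip1 rose 1.64-fold and 2.08-fold, and 2 of 26 genes of that list rose. Atf3, a stress-induced transcription factor, rose 1.77-fold, against the direction of its integrated stress response list, and Tgfb1, the growth factor TGF-beta, 1.55-fold. Keap1, the inhibitor of the oxidative stress regulator NRF2, fell to 0.733 of the control level. Of 11 neural and glial markers 1 rose, the growth cone gene Gap43 (1.61-fold), and 1 fell. Of 39 integrin, cadherin and motility genes 1 fell, the adhesion gene Alcam (to 0.715), and 1 rose. The median, mean and camera direction of a list differed in sign for skeletal muscle, Wnt target, adipocyte, Hox, heat shock and mesenchymal transition genes.

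The number of calls was compared with other groupings of the same libraries. Without pairing, the real grouping called 0 genes and another of the 10 splits called 3, so all 10 splits called at least as many. For gene lists, 5 of the 10 splits gave as many as the real one, which gave 10, and the highest other split gave 19. For chromosomes 3 splits gave as many, with 1 in the real and 3 in the highest other. With pairing, 1 of the 4 splits that part every pair gave as many genes as the real grouping, the real one itself, with 298 genes against 0 in the others, which exchange control and knockout within 1 or 2 pairs. For lists in the paired test the count was likewise 1 of 4, with 12 lists against 8. Splits this few cannot give a share under 0.05.

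The interferon list was higher in knockout replicates 2 and 3 but not in replicate 1. The other genes argue against a wrong label on knockout replicate 1 but do not exclude it. Of 636 genes called from pairs 2 and 3 alone, 81.0% went the same way in pair 1. These genes lay outside the interferon, antigen presentation and cytokine lists. A wrong label predicts no shared direction if genes vary independently, but genes vary together, so 1 pair may share a direction for another reason. Setd1a stood at 53.2 CPM in knockout replicate 1 and between 71.0 and 75.3 CPM in the controls. Macrophages in the cultures, as the source of these transcripts, are argued against by the median of 18 macrophage genes in the knockout libraries, 0.0458 CPM, while all 18, of which 3 passed the low-count filter, went from 22.7 ± 1.11 to 26.2 ± 3.602 CPM in sum and the interferon genes from 1052 ± 278 to 1955 ± 957 CPM (SD, n = 3; exact two-sided permutation p = 0.2 and 0.3); other immune cells were not tested. Variation between libraries that is unrelated to the knockout stays open. The list mean ranged over 1.19 log2 units among the control libraries alone, against 1.04 between the group means. A range over 3 libraries and a difference of means are unlike measures, and the comparison leaves out the pairing. Setd1a stood at 53.2, 68.7 and 56.3 CPM in knockout replicates 1, 2 and 3, and the list mean at 3.10, 4.97 and 4.97 log2 CPM. The knockout library with the least Setd1a transcript thus had the lowest list mean. The interferon difference may still come from variation between libraries, and an effect of the knockout that appears in some libraries was not tested.

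Camera called mitochondrially encoded transcripts higher and ribosomal protein transcripts lower in the knockout, with the preset correlation only. GC content and length as the whole cause are argued against, since both lists were still called in the paired test with an offset for them (larger adjusted p = 0.000155 with the preset correlation; with an estimated one neither was called, at 0.544 and 0.523 before and 0.675 and 0.694 after), with mean log2 changes of 0.28 after and 0.33 before for mitochondrial genes and of -0.08 after and -0.11 before for ribosomal proteins. Damaged cells that retain mitochondrial RNA stay open: the mitochondrial share was higher in every knockout library than in any control. The changes of the 6 mitochondrial mRNAs with over 1000 CPM in the controls were unequal (exact permutation p = 0.000189), from a log2 change of 0.62 for mt-Nd2 to 0.18 for mt-Cytb, which did not pass the test, but the bound set first, that damage raises them evenly, was an assumption and how evenly it does so was not measured. An effect of the knockout stays open and was not tested.

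A further hypothesis was that mitochondrial translation factors fell as a group, since Gatb and other lower genes belong to them. Of 48 such genes not seen before, 38 lay below 0, with a median log2 change of -0.12 and 1 called. Camera in the paired test gave an adjusted p of 0.00041 over the 2 added lists, and 0.000616 with the GC and length offset. With an estimated correlation the adjusted p was 0.092. That version of camera also uses fewer degrees of freedom, so its larger p need not come from correlation between the genes. Whether these genes fell jointly stays open. A hypothesis that neuronal genes repressed by the factor REST rose as a group came from genes such as L1cam and Syn1. Of 24 such genes not seen before, 17 lay above 0, with 1 called higher and 1 called lower. Camera's adjusted p of 0.0915 left the hypothesis open. The bound set beforehand, a p that misses the threshold, was too weak to exclude a rise while the median log2 change was 0.09. The lower genes were also examined for divergent promoters. Of 108 protein-coding lower genes, 21.3% had a head-to-head neighbour within 1000 bases, at the 72.3 percentile of 10000 random lists matched on expression, which left that hypothesis open too: the bound set beforehand was the 95th percentile, 25.0%, but the share lay above the random median of 18.5%, within the spread of the random lists. Of 180 higher genes, 5.00% had such a neighbour, below the 5th percentile of the random lists, which was 11.7%; this side was added to the test of the lower genes without a prediction.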
